A study of Homo sapiens with 6 samples.

How the data were processed

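Total RNA was isolated from 6 cultures with a column kit, amplified from the 3' end, biotin-labelled and hybridised to 6 Affymetrix U133 Plus 2.0 arrays, per the labels' protocols. The series consists of 3 cultures labelled MCF-7 with ectopic Snail and 3 labelled MCF-7 with the control plasmid, all grown with 400 ug/mL G418. The titles call them biological replicates and the design text replicate cultures. Whether they came from independent transfections is not given in the sources used here, so p-values measure the spread between these cultures only.

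The deposited values are 1 intensity (probe set signal) per probe set and array, made by the authors with Affymetrix Expression Console and PLIER, per the submitters' processing notes. Versions, the PLIER variant and the normalization between arrays are not given in the sources used here. The intensities are linear: they had medians between 22.3 and 24.5 and highest values between 23634 and 24932. PLIER gives values close to 0 for dim probe sets, so log2 of the bare signal would spread the dim end widely; log2(signal + 16) was therefore used. This scale understates the change of dim genes. On it, array medians lay between 5.26 and 5.34 and upper quartiles between 7.73 and 7.87, and no further normalization was applied. The median log2 difference over all genes was 0.003.

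Of 54675 probe sets, 62 are array controls and were left out of the tests. The platform annotation names 1 gene for 41091 probe sets, several for 1801 and none for the other 11721. Gene symbols were checked through Entrez identifiers against a RefSeq gene table of assembly GRCh38.p14 (41037 probe sets matched; 0 symbols changed). The array gives no genomic positions, and no coordinates are printed. Each of 19775 genes was represented by its single-gene probe set with the highest mean log2 value over the 6 arrays; 9252 genes had 1 such probe set and 10523 had more. Of 6139 genes called with more than 1 probe set, 456 had another probe set called in the opposite direction. Probe sets ending in x_at or s_at can match several transcripts.

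Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, arrays labelled Snail minus control, two-sided, no covariates), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A second count asked for an absolute log2 difference of at least 1. Gene lists were tested with camera (preset correlation between genes 0.01) for 46 lists chosen before the data were examined, which hold 1019 genes, 925 of them measured; 4 older symbols in them were updated. Lists covered junctions, keratins, EMT, the cytoskeleton, adhesion, matrix, the estrogen receptor axis, signalling, metabolism, stress, RNA quality, markers of other cell types and genes lost or silent in MCF-7. camera with an estimated correlation and fry were alternatives.

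No detection calls were used. A background level was set per array as the 95th percentile of 27 probe sets for bacterial control RNAs, and ranged from 9.11 to 21.6. For a gene above this level on all 3 arrays of one group and on no array of the other, the fold is given as a lower bound ("at least"): the bright group's mean against the dim group's mean of, per array, the higher of the background level and the gene's own signal, both as means of log2 values. This rule was chosen after the data were examined.

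The genes named in the Results were chosen by a rule set before the data were examined, apart from those stated to lie beyond it. They are SNAI1; CDH1, CDH2, VIM, FN1, ZEB1, ZEB2, SNAI2, TWIST1, ESR1, KRT8, KRT18, CD44 and CD24 whatever their result; the 10 genes that rose and the 10 that fell most among those past the test, with groups that do not overlap and a mean in the higher group at or above the median of all genes; and from each list described, up to 4 members with the smallest p past the test, or up to 2 with the highest mean where none passed. Y-linked genes and XIST were not named. Most genes named only in the additional observations lie outside this rule.

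Alternatives were quantile normalization, centring each array on its median, pseudocounts of 1 and 32, a filter on genes under the 40th percentile of mean signal, the mean of a gene's probe sets, leaving out x_at and s_at probe sets, eBayes with trend and robust, a plain test with equal variances and no moderation, the replicate number as a block, leaving out each array, a threshold of 0.01, and limma's treat against 1.5-fold. Chosen after the data were examined were 3 settings on a split of the arrays by the signal of the BioB spike-in control, and list tests over genes above background. The spike-in signal of the BioB 5' probe set was 795 to 1075 on Snail 1, Snail 2 and control 2 and 1898 to 2962 on Snail 3, control 1 and control 3. The test was run on simulated data for 19775 genes with 3 arrays against 3. Of 50 genes per size, it recovered 16% at a log2 change of 0.5, 84% at 1, 100% at 2 and 98% at 4. There were 9 false calls (5.70% of calls). The changed genes were drawn from those at or above the median control level, with noise independent between genes. Far fewer genes changed there than were called in the data, so these shares do not describe the comparison itself. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.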

Results

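RNA from 6 cultures was hybridised to Affymetrix U133 Plus 2.0 arrays, 1 array per culture. All cultures are labelled as MCF-7, an established estrogen receptor-positive, luminal breast cancer cell line with epithelial morphology. In 3 cultures the cells had been transfected to express Snail, the zinc finger repressor encoded by SNAI1 that drives epithelial-mesenchymal transition (EMT), and 3 cultures carried the control plasmid. Both groups were grown with 400 ug/mL G418. The study set out to learn what EMT induced by Snail does to cytoskeletal genes and to the physical properties of the cells, so the comparison is that of the arrays labelled Snail with the control arrays. The deposited signals cover 54675 probe sets. Median signals of the arrays lay between 22.3 and 24.5, and between 50.5% and 64.4% of probe sets lay above the level of bacterial control probe sets on the same array. The number of arrays, 3 per group, limits the precision. Differences are in log2(signal + 16), arrays labelled Snail minus control, with the standard error (SE) of the limma fit; adjusted p-values are limma's after Benjamini-Hochberg adjustment.

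SNAI1, the gene of the construct, did not pass the test with all 6 arrays. Its single probe set gave a signal of 37.7 ± 8.82 (SD, n = 3) on the arrays labelled Snail and 37.2 ± 7.33 (SD, n = 3) on the control arrays. The log2 difference was 0.01 (SE 0.16), with an adjusted p of 0.97 in limma. It was 0.39 (adjusted p 0.048) with only the 3 arrays of low spike-in signal (Snail 1, Snail 2 and control 2) and -0.40 (adjusted p 0.11) with the 3 of high signal, fits in which 1 group is a single array. Where this probe set lies relative to the transfected sequence is not given in the sources used here, and a probe set outside that sequence would check nothing. These values do not bear out the label, and the term "arrays labelled Snail" is kept for that reason. Every direction below rests on that label. A line other than MCF-7 in these cultures is a candidate explanation that is taken up further below. A rise or fall is therefore a difference between the groups, not a shown change within MCF-7.

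The profiles of the groups were far apart. Pearson correlations across the 19775 genes, with 1 probe set each, were 0.987 to 0.997 within the arrays labelled Snail and 0.993 to 0.995 within the control arrays. Between the groups they were 0.861 to 0.870. Genes are not independent replicates. Of 19775 genes tested, 9923 (50.2%) differed, 5194 higher and 4729 lower on the arrays labelled Snail. At least 2-fold differences were found for 4739 genes, 2501 higher and 2238 lower, and differences of 16-fold or more for 448 genes. The arrays of the groups did not overlap for 57.5% of all genes, against 10% by chance for 3 against 3. Among the 9923 genes the share was 99.1%, but these were picked by a test on the same arrays, so the 10% does not apply to them. By probe set, 20891 of 54613 differed, 11015 higher and 9876 lower. Of the 9923 genes that differed, 1253 were above the bacterial control level on all arrays of one group and on none of the other, 665 of them on the arrays labelled Snail. With only the 3 arrays of high spike-in signal (Snail 3, control 1 and control 3), 6220 genes and 6909 probe sets differed, and with only the 3 of low signal 9290 genes and 18645 probe sets.

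The 10 genes with the highest log2 differences were near background on the control arrays, and their order depends on the pseudocount, so none is read from it. IRS4, an insulin receptor substrate adaptor, rose by 8.68 (SE 0.13), LDHB, a lactate dehydrogenase subunit, by 8.03, CNN3, an actin-binding calponin, by 7.98, and CDH2, N-cadherin, by 7.91. GSTP1, a glutathione transferase, rose by 7.38, the junction protein gene JAM3 by 7.24, and LIN28B, an RNA-binding protein that blocks let-7 maturation, by 7.12. PSAT1, a serine synthesis enzyme, rose by 7.09, and CCND2, a D-type cyclin, and HOXD10, a homeobox gene, by 7.05 each. LIN28B gave a signal of 0.0097 ± 0.0116 on the control arrays and 2217 ± 250.4 on the arrays labelled Snail (SD, n = 3), at least 160-fold higher; CNN3 was at least 419-fold, CDH2 337-fold, GSTP1 194-fold and PSAT1 176-fold higher. The 10 genes with the lowest differences were likewise near background on the arrays labelled Snail by the probe set used for each. They were TFF1, the estrogen-induced trefoil factor (-8.55; SE 0.22), DSCAM-AS1, a long non-coding RNA of luminal breast cancer (-8.34; SE 0.22), CYB561 (-7.93; at least 361-fold lower), MLPH (-7.89), FXYD3 (-7.74), TSPYL5 (-7.71), EPCAM (-7.58), ESR1 (-7.55), SPTSSB (-7.48) and ESRP1 (-7.38). TFF1 signal was 13.9 ± 10.7 on the arrays labelled Snail and 10799 ± 872 on the control arrays (SD, n = 3). The largest SE among these 20 genes was 0.22. For every gene named below as having risen or fallen, all 3 arrays of one group lay above all 3 of the other. Members of lists are named by smallest p, not by size. As the mean of all its probe sets, 77 of 199 named genes past the test gave a difference smaller by over 1.5 times and ERG turned sign; among the 77 were ESR1 (-0.83), CDH1 (-3.54), CDH2 (4.82), VIM (4.31), ZEB1 (2.65) and ZEB2 (1.65); with a pseudocount of 1, 45 gave one larger by over 1.5 times.

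Most tight junction, simple keratin and epithelial regulator genes fell, while desmosome genes went both ways. CDH1, E-cadherin, had a log2 difference of -6.54 (SE 0.12), from a signal of 5861 ± 347 on the control arrays to 47.4 ± 5.03 on the arrays labelled Snail (SD, n = 3). Of 13 adherens junction genes, 9 fell, 3 rose and 1 did not pass the test (4 rose when adjusted over the list alone); EPCAM (-7.58), CDH3 (-5.32) and NECTIN2 (-2.51) fell with CDH1. The list passed camera with an adjusted p of 0.028, but gave an adjusted p of 0.42 with an estimated correlation, 0.31 without x_at and s_at probe sets and 0.060 without dim genes. Of 22 tight junction and polarity genes 17 fell and 1 rose (2 rose when adjusted over the list alone), with camera adjusted p 1.4e-06 and adjusted p 0.46 with an estimated correlation. MARVELD2 (-6.14), CLDN4 (-5.46), TJP3 (-4.09) and CLDN7 (-3.96) were among those that fell. All 19 measured genes of the list of epithelial regulators and splicing factors fell, among them the splicing factor ESRP1 (-7.38) and the transcription factors GRHL2 (-7.15), ELF3 (-5.83) and ELF5 (-5.07). That list had a camera adjusted p of 3.7e-13 and an adjusted p of 0.22 with an estimated correlation. Of 6 simple keratins 5 fell and none rose, among them KRT19 (-7.13), KRT80 (-6.32), KRT8 (-4.74; SE 0.17) and KRT18 (-4.49; SE 0.19); camera gave an adjusted p of 0.00010, and the adjusted p was 0.46 with an estimated correlation. Desmosome genes went both ways, 7 of 12 falling (PPL, -5.51; JUP, -2.96; PKP1, -2.70) and 4 rising (DSC3, 4.95), and the list did not pass camera (adjusted p 0.19). Of 7 basal and stratified keratins, KRT4 (-4.90) and KRT15 (-2.60) fell and 5 did not pass the test (camera adjusted p 0.19). Counts adjusted over the list alone equal those over all genes wherever none are given.

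**Figure D1:**
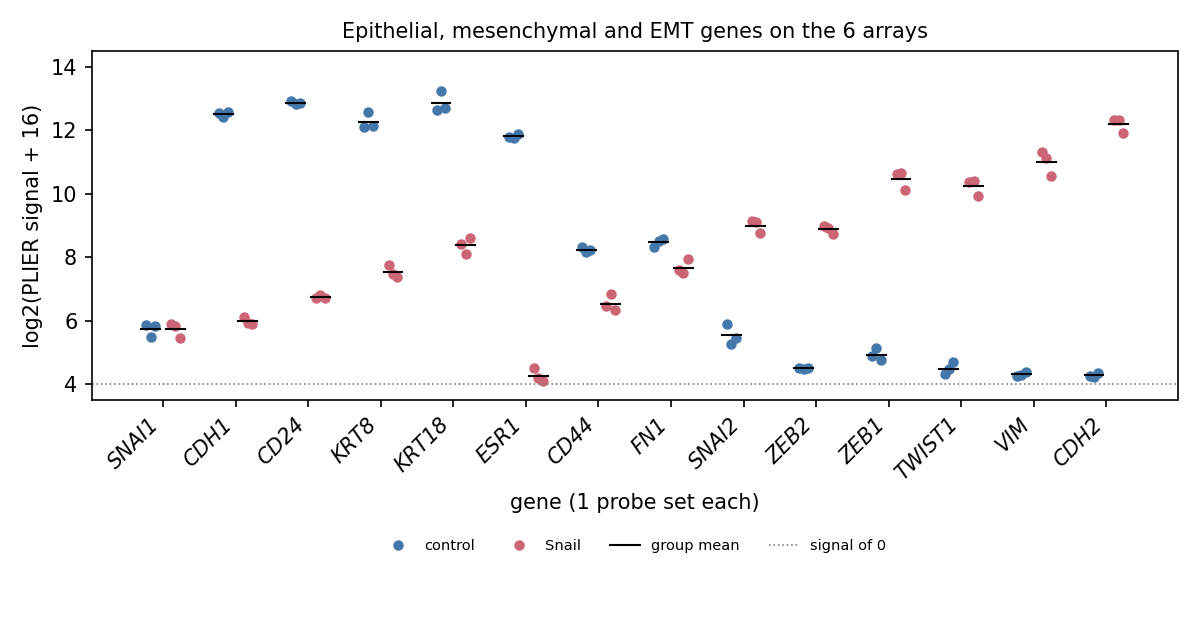
Log2(PLIER signal + 16) of SNAI1 and the 13 EMT and luminal genes chosen before the data were examined; each point is 1 array, blue for control (n = 3) and red for arrays labelled Snail (n = 3), black bars are group means, and the dotted line is a signal of 0. SNAI1 has a log2 difference of 0.01, CDH1 to FN1 are higher on the control arrays (FN1 for its brightest probe set), and SNAI2 to CDH2 are higher on the arrays labelled Snail.

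Most luminal and estrogen-induced genes listed were lower on the arrays labelled Snail. By its brightest probe set ESR1, the estrogen receptor, had a signal of 3.33 ± 3.15 against 3588 ± 153 on the control arrays (SD, n = 3), at least 298-fold lower. Its other probe sets past the test among probe sets went both ways, with differences of -1.08, 0.47, 0.58 and 0.40. Those with 0.47 and 0.58 had signals of 107 to 130 on the arrays labelled Snail and 63.0 to 99.0 on the control arrays. Of 25 genes of luminal identity and the estrogen receptor axis, 19 fell and 5 rose (20 fell when adjusted over the list alone). Camera gave the list an adjusted p of 9.4e-08, and the adjusted p was 0.29 with an estimated correlation. ERBB3, a receptor tyrosine kinase (-6.17), AGR2 (-6.54) and the transcription factor SPDEF (-5.88) fell with ESR1. Of 28 estrogen-induced genes 24 fell and none rose, among the former the chemokine CXCL12 (-5.57), TFF3 (-5.72), IGFBP4 (-6.00) and PKIB (-4.91); the camera adjusted p was 1.4e-12 and the adjusted p 0.42 with an estimated correlation. The surface marker CD24 fell by 6.12 (SE 0.11), and CD44, which marks breast cancer cells with stem cell properties when CD24 is low, fell too, with -1.70 (SE 0.15). Among 14 stem and progenitor markers 7 fell, including ALDH1A3 (-3.63) and KLF4 (-1.68), and 3 rose, including PROCR (2.36); the list did not pass camera (adjusted p 0.19).

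Several EMT transcription factors rose. Log2 differences were 5.75 (SE 0.16) for TWIST1, 5.53 (SE 0.17) for ZEB1, 4.39 (SE 0.12) for ZEB2 and 3.46 (SE 0.18) for SNAI2, the gene of Slug. TCF4 (6.66) and TWIST2 (4.77) rose as well, at least 164-fold and 30.6-fold. Of the 14 measured factors 8 rose and 2 fell, with a camera adjusted p of 0.0065 and an adjusted p of 0.60 with an estimated correlation. Of 25 mesenchymal markers 8 rose, 6 fell and 11 did not pass the test, with a median difference of 0.02 and a mean of 0.80; the list did not pass camera (adjusted p 0.48) and was higher in fry (adjusted p 0.00079). CDH2 was at least 337-fold and VIM, vimentin, at least 148-fold higher; VIM gave a log2 difference of 6.69 (SE 0.19). SPARC (3.75), a matrix glycoprotein, and ACTA2 (2.57), smooth muscle actin, rose too, though SPARC gave 0.61 (adjusted p 0.017) without x_at and s_at probe sets. FN1, fibronectin, depended on the probe set. The brightest gave -0.80 (SE 0.15; adjusted p 0.0015 in limma), while the probe set taken without x_at and s_at probe sets gave 2.78 (adjusted p 2.9e-07), and the mean of its probe sets gave -0.01 (adjusted p 0.97); the arrays of high spike-in signal alone gave -0.52 (adjusted p 0.13). FN1 had 7 probe sets: 4 were called lower, 1 was called higher and 2 did not pass the test among probe sets.

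Cytoskeletal genes, the subject of the study, changed in both directions. Of 45 actin isoforms and actin-binding proteins, 11 rose and 17 fell (18 fell when adjusted over the list alone), and the list did not pass camera (adjusted p 0.43). Its median was -0.26 and its mean 0.29, and fry, which tests whether genes move one way on balance, turned its direction to higher (adjusted p 0.036). Among those that rose were CNN3 (7.98), the actin-bundling or filament-binding genes PLS3 (4.98) and CALD1 (6.92), and MSN, moesin, which links actin to the membrane (6.85). MSN signal was 1.36 ± 1.20 on the control arrays and 1985 ± 111 on the arrays labelled Snail (SD, n = 3). Of 21 myosin and contractility genes 10 fell, among them MYH14 (-3.17, and -0.97 without x_at and s_at probe sets), MYO5B (-2.10, and -1.04 without them), MYO5C (-2.16) and MYL12A (-1.88), and 3 rose (camera adjusted p 0.097). Of 33 tubulins and microtubule-associated proteins 17 rose and 7 fell (18 rose when adjusted over the list alone; camera adjusted p 0.11). TUBB2B (4.86), the end-binding protein gene MAPRE2 (3.39) and MAP1B (2.11) rose. The dynein chain gene DYNC1I1 rose by 3.96, but gave 0.28 (adjusted p 0.32 in limma) without x_at and s_at probe sets. The probe set taken there lay below the background level on all 6 arrays (signals of 0.037 to 11.5), so it cannot speak for or against the rise. Intermediate filament genes other than keratins, with the nuclear lamina, went both ways: 6 of 20 rose and 7 fell (camera adjusted p 0.96). The neurofilament genes NEFL (6.14) and NEFM (5.53) rose with VIM, and LMNA, encoding lamins A and C, fell (-2.21). Among 34 Rho GTPases and regulators 18 fell and 5 rose (7 rose when adjusted over the list alone; camera adjusted p 0.11). RHOF fell (-3.46), whereas RND2 (2.99), CDC42EP3 (2.81) and CDC42EP1 (2.25) rose.

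**Figure D2:**
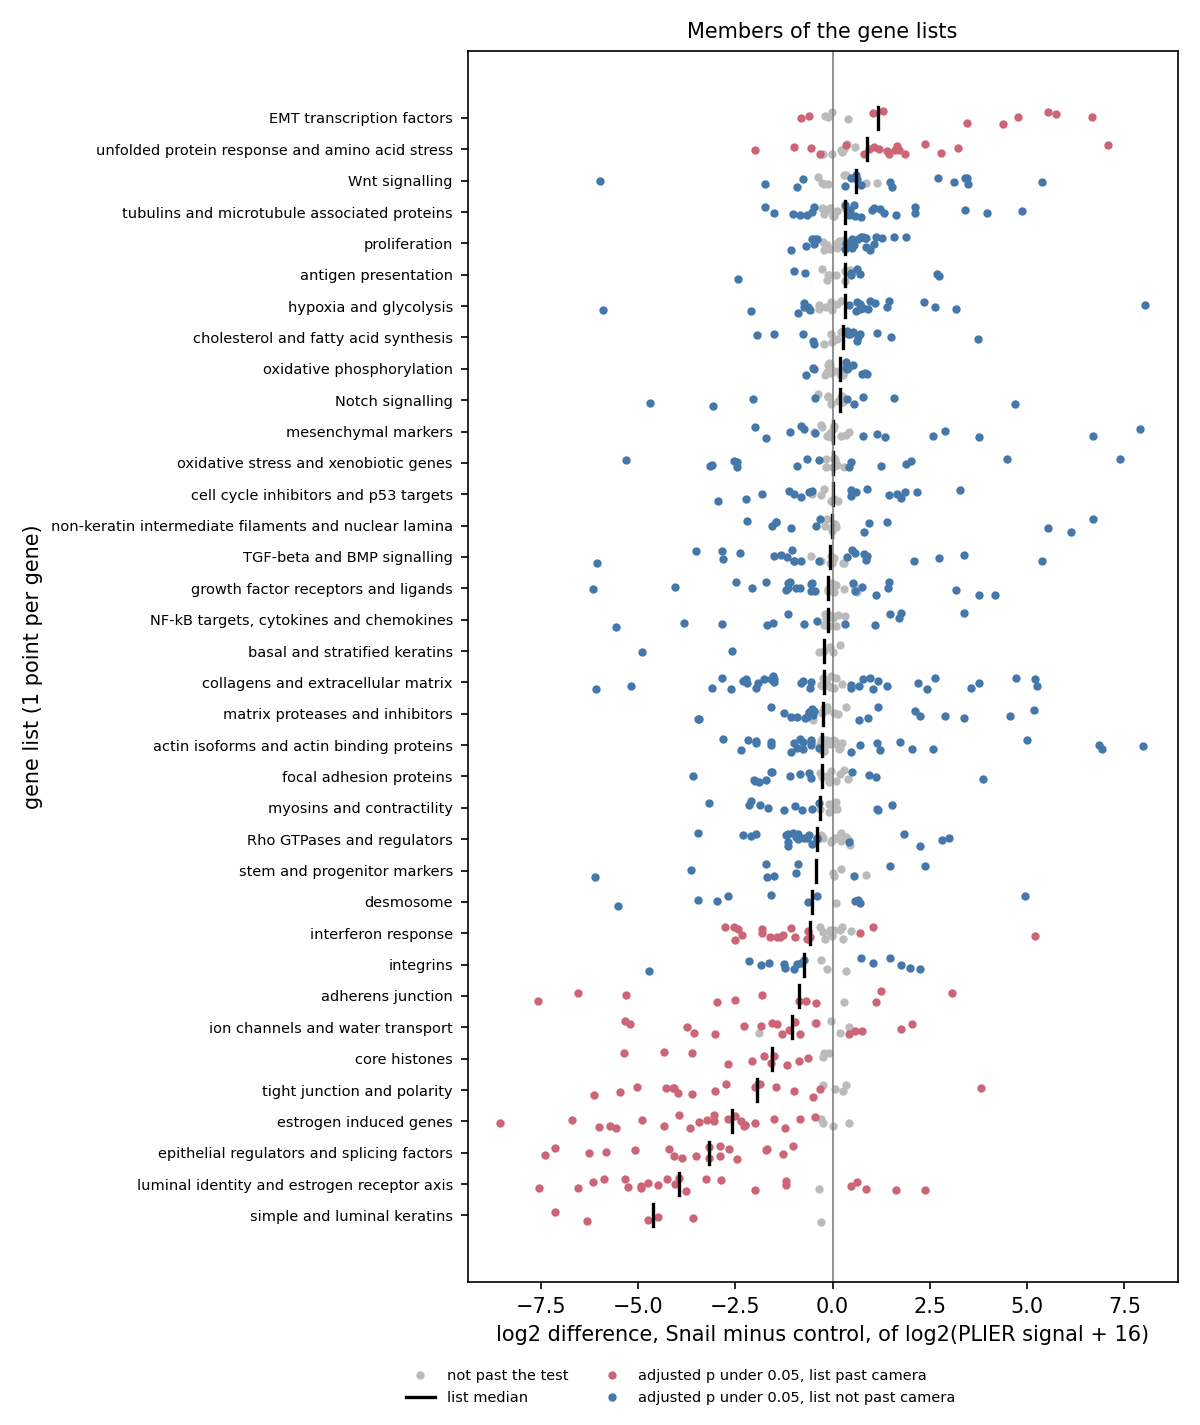
Log2 difference, arrays labelled Snail minus control, of each measured gene of the 36 main lists, ordered by list median (black bar); grey points did not pass an adjusted p of 0.05, and coloured points did, red in lists past camera and blue in the others. Simple keratins and luminal genes lie furthest to the left, EMT transcription factors furthest to the right, and cytoskeletal and matrix lists spread to both sides of 0.

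Adhesion and matrix genes also changed in both directions. Of 19 integrins 10 fell and 6 rose (11 fell when adjusted over the list alone; camera adjusted p 0.31); ITGA3 (-2.16) and ITGB8 (-1.24) fell and ITGA4 (2.25) rose. ITGB4 fell by 4.71, but its probe set taken without x_at and s_at probe sets gave -0.04 (adjusted p 0.88 in limma). That probe set lay below the background level on all 6 arrays (signals of 0.001 to 7.43), so it cannot speak for or against the fall. Of 25 focal adhesion genes 11 fell and 4 rose (5 rose when adjusted over the list alone). NEDD9 (-3.58), CAV1 (-2.03) and TNS3 (-2.01) fell, and PARVB rose by 3.87, but by 0.75 (adjusted p 0.21) with a pseudocount of 1, which takes another probe set. The focal adhesion list did not pass camera (adjusted p 0.11), but did so without x_at and s_at probe sets (adjusted p 0.0096). Of 46 collagens and matrix genes 16 rose and 20 fell (camera adjusted p 0.45). THBS1, thrombospondin 1 (-6.07), and COL12A1 (-5.19) fell, and COL4A1 (5.25) and VCAN (5.19) rose, VCAN with an adjusted p of 0.12 at a pseudocount of 1, from another probe set. Among 32 matrix proteases and inhibitors 9 rose, among them PLAT (4.56), ADAMTS1 (5.18) and SERPINE2 (3.38), and 13 fell, with MMP16 (-3.46). That list had a median of -0.25, a mean of 0.19 and a camera adjusted p of 0.56, and was higher in fry (adjusted p 0.019).

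Signalling lists did not pass camera, though many of their members changed. In TGF-beta and BMP signalling 10 of 31 genes rose and 13 fell (14 fell when adjusted over the list alone; adjusted p 0.53); BMP2 (5.37) rose, and the TGF-beta-induced gene TGFBI (-6.05), TGFB2 (-3.52) and BAMBI (-2.83) fell. In Wnt signalling 14 of 26 rose and 4 fell (adjusted p 0.059, and 0.036 without Snail replicate 3), with the ligand gene WNT5A (5.39), its receptor ROR2 (3.46) and LEF1 (3.13) higher and the Wnt inhibitor DKK1 (-5.97) lower. Of 18 Notch genes 5 rose, with HEY1 (4.70), and 4 fell, with LFNG (-4.68), NOTCH3 (-3.09) and HEY2 (-2.06); the adjusted p was 1.00. Of 33 growth factor receptors and ligands 9 rose, with FGF2 (4.16) and KIT (3.76), and 15 fell, with IRS1 (-4.05) (adjusted p 0.45, and 0.035 without x_at and s_at probe sets). Among 38 proliferation genes 18 rose, among them CCNE1 (1.88), CDC6 (1.57), MCM3 (1.26) and PCNA (1.11), and 6 fell. Camera gave proliferation an adjusted p of 0.059, and 0.046 with a pseudocount of 32. Of 24 cell cycle inhibitors and p53 targets 10 rose, including PMAIP1 (3.28), GADD45A (2.17) and SESN1 (1.87), and 8 fell, including TP53I3 (-2.96) (9 fell when adjusted over the list alone; adjusted p 0.86).

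Stress, immune and metabolic lists were mixed. Of 26 genes of the unfolded protein response and amino acid stress 15 rose and 4 fell (17 rose when adjusted over the list alone; camera adjusted p 0.0028; adjusted p 0.56 with an estimated correlation). They included the serine synthesis genes PSAT1 (7.09) and PHGDH (2.79), the stress factor ATF3 (3.22, and 0.79 without x_at and s_at probe sets) and the cystine transporter gene SLC7A11 (2.36). Of 31 interferon response genes 16 fell, among them IFIH1 (-2.33) and OAS3 (-2.76), and 3 rose, including BST2 (5.19), with a camera adjusted p of 0.00995 and an adjusted p of 0.61 with an estimated correlation. OASL fell (-2.50), but had an adjusted p of 0.11 at a pseudocount of 1, from another probe set. The interferon list gave an adjusted p of 0.071 without dim genes. Of 24 ion channel and water transport genes 14 fell and 5 rose, with the sodium channel gene SCNN1A (-5.33), AQP3 (-5.22), KCNK6 (-3.74) and KCNN4 (-3.56) lower. This list had a camera adjusted p of 0.0075, 0.070 without dim genes, and an adjusted p of 0.42 with an estimated correlation. Of 14 histone genes 11 fell and none rose (camera adjusted p 3e-05; adjusted p 0.42 with an estimated correlation), among them H2BC21 (-5.37), H2BC5 (-4.35, and -1.99 from another probe set with a pseudocount of 1), H2AC6 (-3.62) and H1-2 (-2.06). Histone genes share near-identical sequences, so single members are uncertain.

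The other metabolic and immune lists did not pass camera. In hypoxia and glycolysis 15 of 30 rose and 8 fell (9 fell when adjusted over the list alone; adjusted p 0.31), with LDHB (8.03) and PDK1 (2.63) higher and FBP1 (-5.90) and EPAS1 (-2.10) lower. In oxidative phosphorylation 8 of 25 rose and 3 fell (adjusted p 0.45), by small amounts such as 0.88 for CYCS and -0.67 for COX6C. In cholesterol and fatty acid synthesis 10 of 21 rose and 5 fell (adjusted p 0.43), STARD4 by 3.73 and SREBF1 by -1.94. Oxidative stress and xenobiotic genes rose in 7 of 23 cases and fell in 9 (adjusted p 0.56), with GSTP1 (7.38) and GSTA4 (4.48) higher and NQO1 (-5.32) and CYP1B1 (-3.16) lower. Of 17 antigen presentation genes 6 rose, with TAP2 (2.69), and 3 fell, with TAPBP (-2.42; adjusted p 0.53 for the list). Of 28 NF-kB targets, cytokines and chemokines 6 rose, with IL32 (3.38), and 8 fell, with IL11 (-2.85; adjusted p 0.53 for the list).

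Of the 46 lists tested, 12 passed camera with its preset correlation of 0.01, 3 higher and 9 lower; 8 passed without dim genes (2 higher, 6 lower) and 11 with a pseudocount of 1 (2 higher). None passed camera with an estimated correlation (lowest adjusted p 0.22; 5 lists at an unadjusted p under 0.05), and 39 passed fry. In 8 lists the median and the mean differed in sign.

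Genes known to be lost or silent in MCF-7 were checked as a list chosen before the data were examined. CDKN2A, the cell cycle inhibitor gene encoding p16, gave a signal of 0.00443 ± 0.00577 on the control arrays and 1676 ± 185 on the arrays labelled Snail (SD, n = 3), at least 121-fold higher. MTAP, its neighbour on the chromosome, which is lost together with it in MCF-7, gave 1.46 ± 2.52 and 445 ± 85.4 (SD, n = 3), at least 31.9-fold higher. Of the 9 measured genes 6 rose and 3 fell; GSTP1, VIM and CDH2 rose from background, and EGFR rose by 1.42. CDKN2B, which lies beside CDKN2A, was higher on the control arrays (-1.41; SE 0.16), where its signal was 510.0 ± 49.0 (SD, n = 3), as was CAV1 (-2.03), and AXL (-0.45; adjusted p 0.036) was dim in both groups, with signals of 2.88 and 9.68. MTAP, CDKN2B, EGFR and AXL are named beyond the rule for named genes because all measured members of this list are given. CASP3, also on the list, was not among the measured genes. Several of these values rest on the probe set. The other CDKN2B probe set lay below background on all control arrays and gave 0.03 (adjusted p 0.95 in limma among probe sets). MTAP gave -1.15 (adjusted p 0.027) with a pseudocount of 1, which takes another probe set, and EGFR gave -0.08 without x_at and s_at probe sets. A dimmer EGFR probe set without these endings gave 0.91 and was called higher among probe sets, and no EGFR probe set was called lower. On the main scale that MTAP probe set gave -0.78 and was called lower. The other MTAP probe sets gave 4.72, 4.25, 1.84, 1.07 and 0.67, and all of these were called higher. The list passed camera with an adjusted p of 0.035, but gave 0.17 without x_at and s_at probe sets, 0.11 with a pseudocount of 1, 0.054 without dim genes, 0.071 and 0.098 on the arrays of low and of high spike-in signal, and an adjusted p of 0.62 with an estimated correlation.

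**Figure D3:**
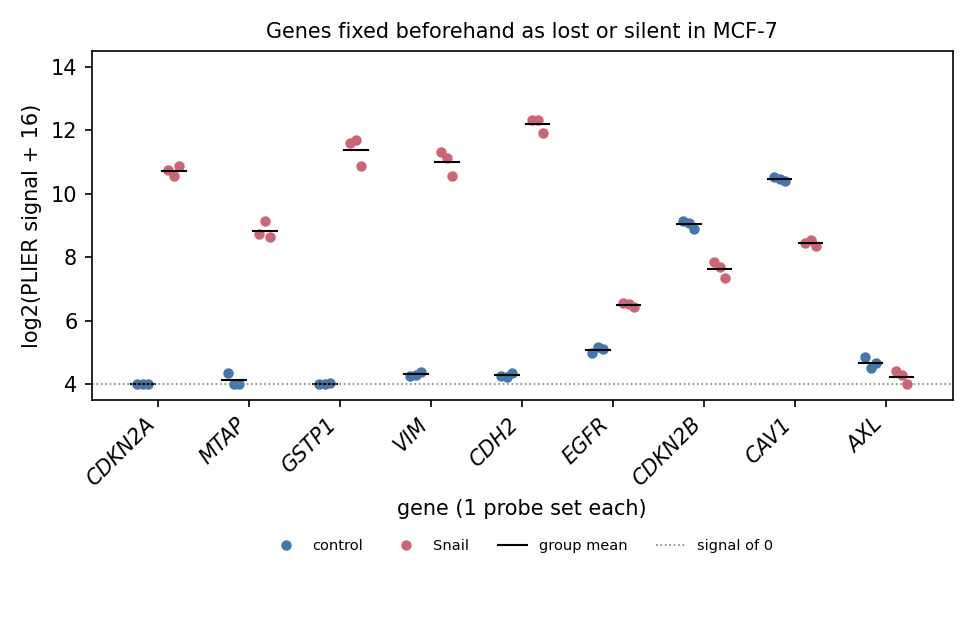
Log2(PLIER signal + 16) of the 9 measured genes listed before the data were examined as lost or silent in MCF-7; each point is 1 array, blue for control (n = 3) and red for arrays labelled Snail (n = 3), black bars are group means, and the dotted line is a signal of 0. CDKN2A, MTAP, GSTP1, VIM and CDH2 lie near a signal of 0 on the control arrays and far above it on the arrays labelled Snail, and CDKN2B and CAV1 are higher on the control arrays.

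None of the lists of markers of other cell types passed camera. Of 12 fibroblast markers 3 fell, COL1A1 (-2.20), COL6A3 (-1.51) and LUM (-0.74, and -0.22 with an adjusted p of 0.31 without x_at and s_at probe sets), and none rose (adjusted p 0.56). Of 11 myeloid markers LYZ fell (-0.63), though it gave 0.02 without x_at and s_at probe sets, and 10 did not pass the test (adjusted p 0.58). Of 10 lymphocyte markers CD79A fell (-0.65), though it gave -0.17 (adjusted p 0.31) as a mean of its probe sets, and 9 did not pass (adjusted p 0.78). Of 11 endothelial markers EMCN fell (-2.16), and ERG gave 0.36 (adjusted p 0.045), lost in most alternatives and -0.32 as a mean of its probe sets (adjusted p 0.88 for the list; none rose when adjusted over the list alone). Among 10 basal and myoepithelial markers 3 rose, including ACTA2, and 3 fell, CDH3, CAV1 and LAMB3 (-1.76; adjusted p 0.78 for the list).

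The lists for RNA quality and reference genes did not pass camera. Of 21 ribosomal protein genes RPL3 rose by 0.53, a call lost with a pseudocount of 1 (adjusted p 0.058) and when adjusted over the list alone (none rose), and 20 did not pass the test (camera adjusted p 0.53). Of 18 reference genes 5 rose, including HPRT1 (0.88) and PGK1 (0.70, and 1.33 without x_at and s_at probe sets), and 2 fell (adjusted p 0.61). Of 14 immediate early genes 8 fell, with JUNB (-3.60), EGR3 (-3.24) and IER3 (-3.09), and 3 rose, with ATF3 (9 fell when adjusted over the list alone; adjusted p 0.10). Of 9 heat shock genes 3 fell, with HSPB1 (-6.86) and BAG3 (-1.03), and 2 rose, HSPD1 (0.50, and 1.76 without x_at and s_at probe sets) and DNAJA1 (1.06; 4 fell when adjusted over the list alone; adjusted p 0.58 for the list). DNAJA1 gave 0.18 (adjusted p 0.25) as a mean of its probe sets. The GAPDH signal at the 5' end was 7.29% of that at the 3' end on array Snail 3, and between 29.9% and 37.8% on the other 5 arrays. For ACTB this ratio was 0.15% on Snail 3 and between 0.51% and 1.35% on the other 5. It was lowest on Snail 3, control 1 and control 3, the arrays of high spike-in signal, and the cause was not tested. Without Snail replicate 3, 10622 genes differed.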

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

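The split by spike-in signal and the list test over genes above background were chosen after the data were examined; the other alternatives were set before. The count of changed genes, 9923, lay between 7949 (adjusted p under 0.01) and 10622 (without Snail replicate 3) under the alternatives other than the high spike-in arrays alone. With only those 3 arrays 6220 genes and 6909 probe sets passed, and with the 3 low ones 9290 and 18645; each has a group of 1 array, and the cause of the difference was not tested. The replicate block gave 9664 genes and 13 lists, with Wnt signalling added. Replicate numbers did not pair the cultures: same-number arrays correlated at -0.13 to 0.11 in their deviations from the group means, and 1 of the 3 arrays labelled Snail correlated best with its own number. The block ended the calls of ERG and INA and of no other named gene. No scaling moved the median of all genes by more than 0.1. Of 3778 values of named genes under alternatives, 3696 kept direction and side of the threshold, 61 lost the call, 3 gained it and 18 turned sign. The list tests were not run with the plain test, which has no list form here, and the probe rules do not apply to probe sets. With an estimated correlation between genes camera called 0 lists, so all 12 calls were lost; fry, which tests for a shift without comparing with other genes, called 39.

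SNAI1, with a difference of 0.01, turned sign with quantile normalization (-0.028), centring (-0.0081), the spike-in split as a block (-0.0026) and the high spike-in arrays only (-0.40, adjusted p 0.11), and ranged from -0.11 to 0.15 when single arrays were left out. With only the low spike-in arrays it gave 0.39 (adjusted p 0.048; range over its alternatives 0.048 to 0.99). The cause was not tested. Dim genes are limited by background: with a pseudocount of 1 the 2-fold count was 5731, and with 32 it was 4159.

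Other signs turned where another probe set was taken. These were FN1 (2.78), CXCL2 (-0.20), LYZ (0.022), EGFR (-0.078) and PAX8 (-2.80) without x_at and s_at probe sets, ERG (-0.32) and PAX8 (-0.46) as means of probe sets, and MTAP (-1.15) and AXL (0.58) with a pseudocount of 1. PAX8 did not pass the test by its brightest probe set. By that probe set it also gave -0.0054 without Snail replicate 3 and -0.14 on the low spike-in arrays only. It ranged from -0.0054 to 0.25 with single arrays left out, and the cause was not tested.

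Direction here is that of the test, which for camera compares a list with the other genes, so the mean need not turn with it. Lists that turned direction passed camera neither before nor after, apart from the actin list (mean 0.29) and matrix proteases (0.19), which passed fry as higher. Means under the turning alternatives were as follows, and the cause was not tested. Notch signalling (mean -0.10) gave -0.14 with quantile normalization, -0.12 with centring, 0.11 as means of probe sets, 0.082 without x_at and s_at probe sets, -0.10 with the replicate block and -0.086 on low spike-in arrays. Intermediate filaments (0.64) gave 0.91 with a pseudocount of 1, 0.46 as means of probe sets, 0.39 without x_at and s_at probe sets and 0.61 on low spike-in arrays. Endothelial markers (-0.14) gave -0.19 with a pseudocount of 1 and -0.016 on high spike-in arrays, ribosomal proteins (0.13) 0.0050 with the spike-in block, 0.0035 on low and 0.0065 on high spike-in arrays, and myeloid markers (-0.13) -0.0043 on high ones. Without dim genes, antigen presentation gave -0.0072 and basal markers (-0.43) -0.37; basal markers gave -0.39 on low spike-in arrays. Without x_at and s_at probe sets, cell cycle inhibitors gave -0.16, oxidative stress genes 0.72 and heat shock genes 1.19. With single arrays left out, the mean ranged from 0.62 to 0.66 for intermediate filaments, -0.14 to -0.034 for Notch signalling, -0.18 to -0.081 for endothelial and -0.15 to 0.023 for lymphocyte markers.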

Other observations

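The gene families in this paragraph and the next were picked after the data were examined, 15 in all, some because HOXD10 and LIN28B were among the genes with the highest differences, and the test of a mixture of cells and the marker list counts over part of the genes were chosen then too. The family counts describe these values and test nothing; "random" counts are medians over 10000 lists of the same size and mean level, and genes of one cluster can be regulated together. Of 28 homeobox genes of the HOX clusters, which set position along the body axis, 21 rose and 1 fell, against a random 9 rising. In the HOXD cluster 6 of 8 rose (random 2), with HOXD13 (log2 difference 6.84; SE 0.14) and HOXD9 (6.25; SE 0.16) rising from background. In the HOXB cluster 8 of 10 rose (random 4), HOXB9 by 3.34 (SE 0.22), and in the HOXC cluster 6 of 9 (random 3), HOXC4 by 2.64 (SE 0.16). The oncofetal RNA-binding protein genes IGF2BP1 (4.54; SE 0.11) and IGF2BP2 (4.24; SE 0.19) rose with LIN28B, 4 of 5 in all (random 2). Of 425 zinc finger genes with ZNF symbols 181 rose and 93 fell, against a random 137 rising.

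Of 15 protocadherin beta genes, adhesion molecules of neurons encoded in a cluster, 12 fell and none rose, among them PCDHB16 (-4.18) and PCDHB2 (-2.66), against a random 3 falling; members of this cluster are alike in sequence, and cross-hybridisation between them was not tested. Of 57 RAB genes of vesicle traffic 29 fell and 9 rose, against a random 16 falling. Of 11 annexins, calcium-dependent membrane-binding proteins, 1 rose and 7 fell (random 3), among the latter ANXA9 (-6.44, SE 0.16). Of 19 S100 calcium-binding protein genes 1 rose and 8 fell (random 4), among the latter S100P (-7.09, SE 0.14) and S100A6 (-4.98, SE 0.16). Of 12 protocadherin gamma genes 0 rose and 3 fell (random 2 and 2), of 19 SOX genes 5 rose and 4 fell (random 4 and 4), of 19 ALDH genes 9 rose and 6 fell (random 6 and 6), of 7 MAGEA genes none changed (random 0 and 1), and the single HOXA gene measured rose (random 0).

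By their brightest probe sets, CDKN2A and MTAP, which lie in a region deleted in MCF-7, were near a signal of 0 on the control arrays. They were high on the arrays labelled Snail. In all, 7 of their 9 probe sets were called and raised, which argues against cross-hybridisation of single probe sets. A mixture with 5% or more control-like MCF-7 cells would keep 5% of each luminal transcript, but 6 of the 10 brightest luminal genes were below that with background as the floor, among them GREB1 (0.75%) and KRT8 (3.41%); TFAP2C (5.27%), GATA3 (7.15%), XBP1 (24.8%) and FKBP4 (100.9%) were above. A line other than MCF-7 in these cultures is a candidate explanation: the 31 expressed genes around RPS6KB1 and around ZNF217, both amplified in MCF-7, had median differences of -1.45 and -1.02, at or below the 0.893rd percentile (0.892954) of 9183 windows, with gene order from GRCh38.p14. Ectopic Snail in MCF-7 cells is the cause that the design names. Cells that were still MCF-7 would be expected to keep both amplified regions. Window medians of -1.45 and -1.02 argue against that cause for the genes around RPS6KB1 and ZNF217. A deleted gene cannot be induced, but neither the deletion nor the amplification was measured here, so ectopic Snail in MCF-7 cells is not excluded. By its brightest probe set CDKN2B, beside CDKN2A, was above background on the control arrays (signal 510.0) and lower on the arrays labelled Snail (-1.41). These values do not bear out a loss that reaches CDKN2B, but they rest on that probe set alone. The other CDKN2B probe set lay below background on all control arrays and gave 0.03 (adjusted p 0.95 in limma among probe sets). MTAP turned sign with a pseudocount of 1 (-1.15), where another probe set is taken. All MTAP probe sets other than that were called higher on the main scale.

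Which line it may be was tested with 2 marker lists written after the values of CDKN2A, MTAP, CD44, HOXD10 and LIN28B were seen, but before the lists were counted. Of 16 measured genes described in HEK293, a human embryonic kidney line with neuronal features, 11 rose and 1 fell (INA, -0.32, a call lost with the replicate block), against a random median of 5 and a 95th percentile of 8 rising (share 8e-04); among the 13 that are in no other list 9 rose and none fell, against a median of 4 and a 95th percentile of 7, and without HOX and IGF2BP genes 5 of 9 rose, no more than the 95th percentile of 5 (share 0.060). The most abundant that rose were ZIC2 (signal 2908 against 489.9 on the control arrays) and HOXD9 (1385 against 2.30). NEFL (1218 against 1.58) and HOXC10 (1158 against 268) came next. PAX2 (0.42, adjusted p 0.12) and, by its brightest probe set, PAX8 (0.12, adjusted p 0.57) did not pass the test. Without x_at and s_at probe sets PAX8 gave -2.80 (adjusted p 1.1e-07 in limma). In that setting 8 of 13 genes rose and EYA1 and DPYSL3 lost their calls. The PAX8 probe sets with -2.80, -0.78 and -0.60 were called lower among probe sets (adjusted p 3.4e-07, 0.0039 and 0.0058 in limma). No PAX8 probe set was called higher, and the others did not pass the test. Of 18 genes of mesenchymal breast cancer lines 3 rose (ETS1, 4.02; EGFR, 1.42; MET, 0.76) and 12 fell, among them LGALS1 (signal 90.3 against 2278) and TGFBI, against a random median of 5 rising, which argues against such a line; of the 7 in no other list 1 rose and 5 fell. No reference arrays of other lines were used here, so HEK293 stays open, neither shown nor excluded. A mislabelled or overgrown culture stays open too. On the arrays labelled Snail, CDKN2A had signals of 1479 to 1846 and MTAP of 383 to 543. These values argue against a clone of cells in which the region of CDKN2A and MTAP is deleted. The deletion was not measured here, so a clone of cells without it is not excluded. An MCF-7 clone would be expected to keep the amplified regions, and the window medians of -1.45 and -1.02 argue against that.

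SNAI1 did not pass the test with all 6 arrays, and gave 0.39 (adjusted p 0.048) on the low and -0.40 (adjusted p 0.11) on the high spike-in arrays, fits in which 1 group is a single array. With 1 probe set for the gene on the array, an ectopic transcript outside that probe set cannot be told apart from a culture without the construct.

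The BioB spike-in signal split the arrays into Snail 3, control 1 and control 3 against the rest. With that split as a block, 96.8% (96.8054) of the called genes kept their call and direction, which argues against the split as the cause of the calls. The real grouping gave 9923 genes and was the 1 of 10 splits of the 6 arrays into 3 and 3 with as many; the highest of the others gave 0. Splits of 3 against 3 are too few for a share under 0.05.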
